A study of Komagataella phaffii GS115 with 3 samples.

How the data were processed

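RNA-seq was carried out on 3 samples of the methylotrophic yeast Komagataella phaffii (formerly Pichia pastoris), strain GS115, a histidine auxotroph widely used as an expression host. The labels give 1 untreated GS115 culture, 1 GS115 culture treated with hydrogen peroxide (H2O2) and 1 hmt-deficient GS115 culture grown without treatment. Each group holds 1 library. Dose and duration of the H2O2 treatment, culture medium and the gene meant by hmt are not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol, depleted of ribosomal RNA, fragmented and made into stranded libraries for paired-end Illumina sequencing.

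The values used are FPKM (fragments per kilobase of gene, scaled to the library's fragment total) per gene, as deposited by the authors and named per the file headers. The submitters' processing notes name FastQC 0.12.1, Trimmomatic 0.39, HISAT2, featureCounts and HTSeq, with no roles or order. The genome build and the annotation were not given in the sources used here. Beside FPKM, the authors deposited a column headed as normalized for both non-control libraries. That column equalled the FPKM column for all 5040 genes of the H2O2-treated library. In the hmt-deficient library it was FPKM times 1.14, which brought its total to 1070995, that of the H2O2-treated library. The untreated library had no such column. FPKM was therefore used for all 3 libraries, and the normalized columns served as an alternative.

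All 5040 gene identifiers are locus tags, and all 5040 were found in the RefSeq gene table of assembly ASM2700v1. That table repeats the locus tag as the symbol for every gene, so neither it nor the files pair an identifier with a gene name or product. The 34 gene lists fixed before the data were examined (antioxidant systems, methanol utilisation, chaperones, ribosome, methyltransferases and others) matched 0 genes, so no pathway is described. Because the authors' build was not named, the table was used only for gene lengths and for the order of genes along chromosomes, and no coordinates are printed. The reference length is a multiple of 3 for all but 393 genes (7.80%) and is called coding length.

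Multiplying FPKM by coding length gave whole numbers of fragments once each library's total was fitted. The fitted totals were 15358161 fragments for the untreated, 22354255 for the H2O2-treated and 18281732 for the hmt-deficient library. Among genes with a coding length divisible by 3 whose rounding allowed the check, 97.3% of 1754, 96.5% of 200 and 94.7% of 342 genes came within 0.1 of a whole fragment, in that order. Over all lengths the shares were 93.0% of 1864, 88.6% of 220 and 87.3% of 378 genes. For lengths divisible by 3 and under 3000 fragments, the agreement of values with whole numbers (the mean resultant length of their fractional parts taken as angles) was 91.4% or more of what rounding allows, in each of 5 bins of coding length in each library. Whether the authors scaled by all mapped fragments or by those assigned to genes is not given in the sources used here. The fragments recovered over all listed genes came to 99.3%, 103% and 102% of the fitted totals. These shares hardly depend on the total that is fitted. They bear on what FPKM was scaled by and do not check the fitted totals. In the untreated library 9 values above 0 carried 3 or fewer decimals, and 0 of these 9 came out whole. They were kept, and counts without them are among the alternatives. At the median coding length, 10 FPKM corresponded to 184, 268 and 219 fragments in the untreated, H2O2-treated and hmt-deficient library. Intervals on ratios are exact 95% intervals computed from the recovered fragments. A value of 0 is bounded with a floor of 3 fragments. Intervals and floors cover counting error only.

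For each pair of libraries the log2 ratio of FPKM plus a pseudocount of 1 was taken over genes with at least 10 FPKM in at least 1 of the pair, and genes were counted at a difference of 2-fold or more. Such log2 values understate the change of low genes. With 1 library per group there is no replicate check, and no p-value or standard error between conditions was computed. A gene group's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries. The lists drew genes singly and so do not reflect any correlation between neighbouring genes. Both comparisons with the untreated library share it, so the correlation and overlap of their ratios were set beside 200 simulations of unchanged libraries. Those simulations assumed a log2 SD of 0.735 per library, which is the SD of the hmt-deficient to H2O2-treated log2 ratio divided by root 2 and so also holds any real difference between these libraries. Gene order was shuffled 1000 times, and lengths were shuffled 2000 times among genes of like expression.

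Before the data were examined, the rule for naming genes took the 10 highest and the 10 lowest with an informative product name. No product names could be attached, so only the 2 highest and the 2 lowest log2 ratios of each comparison are named, by locus tag. A pair of genes listed at 0 in the hmt-deficient library members of long runs of neighbouring genes and members of a few small counts were chosen after their values were seen. The groupings by chromosome end, coding length, expression level and near-silent state were also chosen after seeing the data. The alternatives were other pseudocounts, minimums, thresholds and scalings, counting intervals, the authors' normalized columns, other numbers of genes per chromosome end and each end left out.

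On simulated data for the H2O2-treated against untreated comparison (4897 genes), the counting step recovered 100% of 200 genes changed 4-fold, called 0 unchanged genes, and its 95% intervals covered 95.1% of true ratios. These simulated data held counting noise only, with no variation between cultures or libraries. They check the calculation and not how many of the genes counted below reflect the condition. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.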

Results

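Transcript levels of 5040 genes were measured by RNA-seq of ribosome-depleted RNA in 3 libraries of K. phaffii, 1 each from untreated GS115, H2O2-treated GS115 and an hmt-deficient GS115 strain. The fragment total by which FPKM was scaled, recovered from the values, was 15358161 in the untreated, 22354255 in the H2O2-treated and 18281732 in the hmt-deficient library. Median FPKM was 69.8, 51.1 and 68.3 in the same order. Of the 5040 genes, 4885, 4716 and 4946 reached 10 FPKM. The 10 highest genes took 8.36% of the summed FPKM in the untreated, 13.9% in the H2O2-treated and 8.91% in the hmt-deficient library. With 1 library per group no difference below has a replicate check, and the intervals given cover counting error only. Genes are named by locus tag, because the tables used pair no tag with a gene name.

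The first comparison asked which transcripts differed after exposure of GS115 to H2O2, an oxidant. PAS_chr2-1_0016 stood at 19.7 FPKM in the untreated and 2845 in the H2O2-treated library, a 144-fold difference (95% counting interval 126 to 166). PAS_chr3_1145 was 167-fold higher (137 to 204), at 3.11 against 519 FPKM. In the other direction, PAS_chr3_0440 stood at 6428 FPKM untreated and 6.26 FPKM treated, 1028-fold lower (903 to 1174). PAS_chr1-1_0108 was 293-fold lower (213 to 415), at 1288 against 4.39 FPKM. In the hmt-deficient library these 4 genes stood at 27.9, 219, 1158 and 178 FPKM, in the order given.

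Among 4964 genes past the minimum, 441 were at least 2-fold higher and 1283 at least 2-fold lower after H2O2, together 34.7%. At 4-fold the numbers were 129 and 342. The median log2 ratio of all these genes was -0.38. Of the genes past 2-fold 25.6% were higher, and 21.9% after rescaling to TPM (395 higher, 1410 lower) or 26.8% after scaling without the 20 highest genes of any library (459, 1251). Relative to the median shift, 767 genes were higher and 743 lower (50.8% higher). By construction this puts equal numbers of genes above and below 0, but it does not fix the numbers past 2-fold. The shift was spread unevenly over expression levels. In the lowest of 5 equal bins of mean expression the median log2 ratio was -0.76, and 389 of 1000 genes were at least 2-fold lower against 84 higher. The next bins had medians of -0.55, -0.41 and -0.14. In the highest bin the median was 0.03, with 181 genes higher and 182 lower. Near-silent genes moved both ways: 18 of the 79 genes under 5 FPKM in the untreated library reached 20 FPKM or more after H2O2, while 38 of the 119 genes under 5 FPKM after H2O2 stood at 20 or more untreated.

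The second comparison set the hmt-deficient strain against untreated GS115. The labels tie hmt to no locus tag, so the level of the affected gene could not be read as a check of the label. The hmt-deficient library listed 3 genes at 0, and the untreated and H2O2-treated libraries 4 each. Among the 3 were PAS_chr1-4_0287 and PAS_chr1-1_0102, chosen after their values were seen. PAS_chr1-4_0287 stood at 38.1 FPKM in the untreated and 42.8 in the H2O2-treated library. At the untreated level 1509 fragments would have been counted in the hmt-deficient library, and a floor of 3 fragments (0.0757 FPKM) makes it at least 503-fold lower. PAS_chr1-1_0102 stood at 19.9 and 22.3 FPKM, with 644 fragments expected, and was at least 215-fold lower than untreated (floor 0.0927 FPKM). They were the only 2 at 0 among 4637 genes with 10 FPKM or more in both other libraries. The next lowest of these genes kept 10.8% of the lower of its other levels.

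PAS_chr3_0002 was 199-fold higher in the hmt-deficient library (170 to 235), at 1117 against 5.61 FPKM. PAS_chr3_0015 was 225-fold higher (172 to 301), at 384 against 1.70 FPKM. After H2O2 the same 2 genes stood at 27.7 and 16.2 FPKM. PAS_chr1-4_0481 was 68.8-fold lower (62.8 to 75.4), at 93.7 against 6445 FPKM. PAS_chr1-3_0011 was 50.8-fold lower (48.8 to 52.9), at 78.5 against 3987 FPKM. Both of these were also low after H2O2, at 48.9 and 27.9 FPKM.

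Among 4992 genes, 554 were at least 2-fold higher and 551 at least 2-fold lower in the hmt-deficient strain, together 22.1%, with a median log2 ratio of -0.07. At 4-fold, 166 were higher and 100 lower. Of the genes past 2-fold 50.1% were higher, and 59.8% after rescaling both libraries to TPM (666 higher, 448 lower) or 56.2% relative to the median (618, 482). The authors' normalized column multiplies the hmt-deficient values by 1.14 and has no counterpart for the untreated library; set against untreated FPKM, and so on a different scale, it gave 741 higher and 393 lower (65.3% higher). Unlike after H2O2, the median ratio was nearly level across expression, at -0.08 in the lowest bin and -0.10 in the highest. Genes nearly silent in untreated GS115 were often expressed in the hmt-deficient strain: 39 of 79 genes under 5 FPKM (49.4%) stood at 20 FPKM or more. In reverse, 2 of the 29 genes under 5 FPKM in the hmt-deficient library did so in the untreated one, namely PAS_chr1-4_0287 and PAS_chr2-2_0336, the latter chosen after its values were seen (24.99 FPKM untreated, 1.92 in the hmt-deficient and 0.39 in the H2O2-treated library). Of these 39 genes, 10 (25.6%) lay within 20 genes of a chromosome end, about the share among the 79 low genes they came from (19, or 24.1%).

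Genes at the chromosome ends stood apart in the hmt-deficient strain. Of the 5 outermost genes at each of the 8 ends of chromosomes 1 to 4, 35 passed the minimum, of which 19 were at least 2-fold higher and 0 lower. Among other genes 10.8% were higher and 11.1% lower. The median log2 ratio of the end genes was 1.01 against -0.07 for other genes, above all 10000 random lists matched on expression, whose central 95% ran from -0.36 to 0.27. Those lists drew genes singly, whereas end genes are neighbours, and ratios of adjacent genes correlated at 0.16. The range may therefore be too narrow, as may those of the other comparisons. Median FPKM of the 40 end genes was 24.8 untreated, 27.9 after H2O2 and 64.8 in the hmt-deficient strain. The medians of the 8 ends ran from -0.03 to 4.03. Each lay above the -0.07 of all genes, the lowest only slightly, and among genes past the minimum 6 of the 8 ends held one at least 2-fold higher, while the first end of chromosome 1 and the last end of chromosome 3 held 0. Leaving out any 1 end kept the difference from other genes between 0.97 and 1.11. From the end inward, the median log2 ratio was 1.01 for genes 1 to 5, 0.18 for genes 6 to 10, 0.20 for genes 11 to 15 and 0.38 for genes 16 to 20. It was -0.14 for genes 21 to 50. The absence of lower genes was seen in genes 1 to 5, a window chosen after seeing the data, and did not extend inward. Of genes 6 to 10, 25% were at least 2-fold higher and 12.5% lower. The lower ones included PAS_chr1-3_0011, named above, at rank 6 from an end of chromosome 1. After H2O2, 34 end genes passed the minimum, of which 10 (29.4%) were at least 2-fold higher and 6 (17.6%) lower. Among other genes 8.74% were higher and 25.9% lower. Of the 8 ends, 6 held a gene at least 2-fold higher, the same number as in the hmt-deficient strain. The medians of 6 ends lay above that of all genes. The median of the end genes was -0.08 against -0.39 for other genes, at percentile 98.9 of matched lists. This difference of 0.31 depended on single ends: it was -0.031 without the first end of chromosome 3, 0.62 without the first end of chromosome 1 and 0.68 without the last end of chromosome 2.

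**Figure D1:**
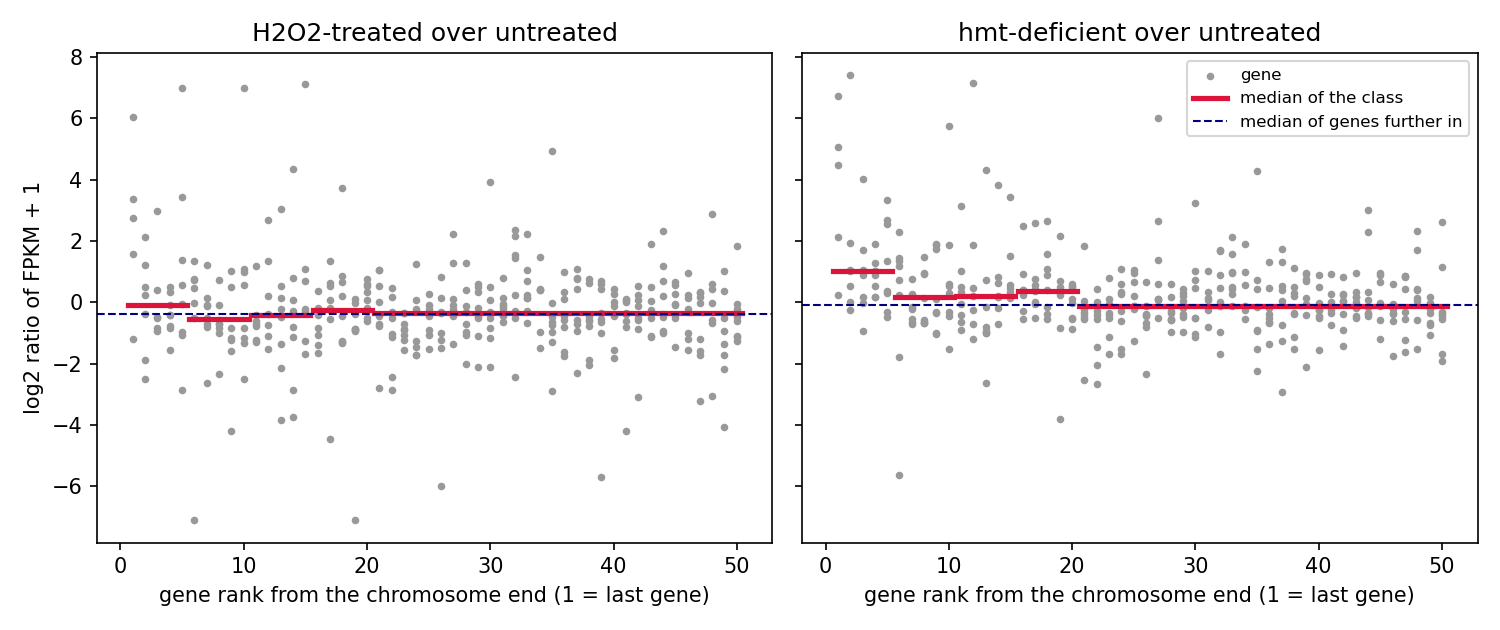
Log2 ratio of FPKM + 1 against gene rank from the nearest chromosome end, for H2O2-treated over untreated (left) and hmt-deficient over untreated (right); each grey point is a gene of 1 library per condition, red bars are medians of rank classes and the dashed line is the median of genes beyond rank 50. In the hmt-deficient strain the median of ranks 1 to 5 was 1.01 against -0.08 beyond rank 50.

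Neighbouring genes formed runs in which each member was at least 2-fold higher or lower. The longest run of higher genes in the hmt-deficient strain held 8 adjacent measured genes, PAS_chr3_0013 to PAS_chr3_0019, at ranks 9 to 16 from an end of chromosome 3. Their median FPKM was 2.09 untreated, 36.5 after H2O2 and 82.1 in the hmt-deficient strain. The first 6 of these genes also formed the longest higher run after H2O2, with a median log2 ratio of 2.86. PAS_chr3_1145 and PAS_chr3_0015, named above, belong to this run. A run on chromosome 1, PAS_chr1-3_0145 to PAS_chr1-3_0149, held 5 genes that were lower in the hmt-deficient strain (median log2 ratio -1.74). It lay within the longest lower run after H2O2, 7 genes with a median log2 ratio of -1.46. Median FPKM of those 7 genes was 64.2 untreated, 19.8 after H2O2 and 28.6 in the hmt-deficient strain. Both comparisons divide by the same untreated library, so runs that coincide in both may come in part from its values. The hmt-deficient comparison had 19 runs of 3 or more higher genes, against a mean of 5.96 (central 95% 2 to 11) when gene order was shuffled, and 12 lower runs against 5.95 (2 to 11). After H2O2 there were 6 higher runs against 3.19 (0 to 7), within the shuffled range, and 85 lower runs against 63.2 (51 to 75).

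**Figure D2:**
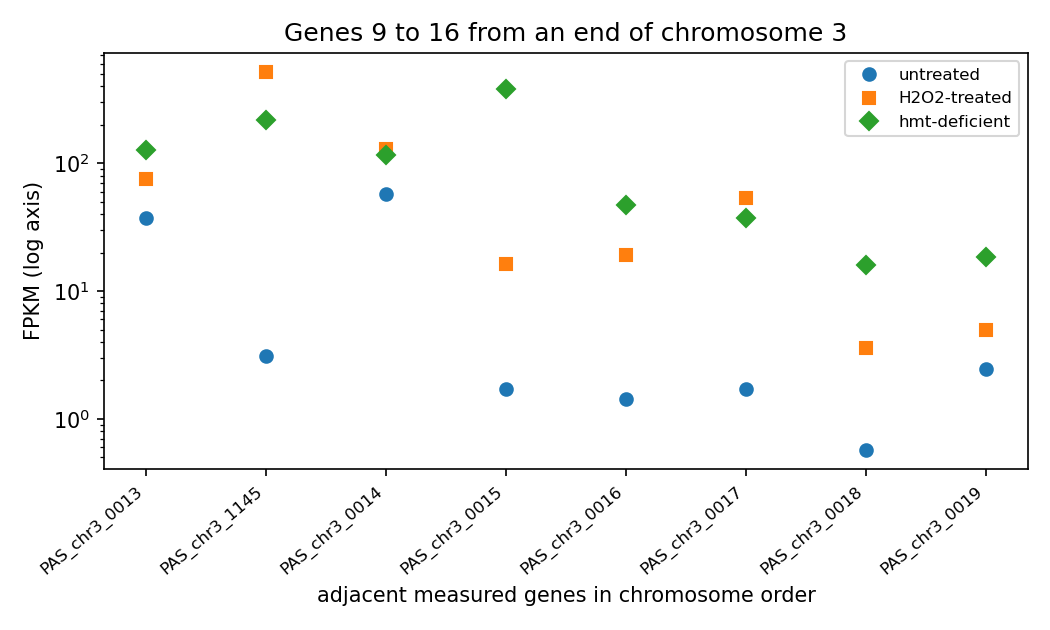
FPKM on a log axis of the 8 adjacent genes from PAS_chr3_0013 to PAS_chr3_0019, in chromosome order, in the untreated (circles), H2O2-treated (squares) and hmt-deficient (diamonds) library, 1 library each. Each gene was lowest in the untreated library; PAS_chr3_0015 went from 1.70 FPKM untreated to 384 FPKM in the hmt-deficient strain.

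The third comparison set the hmt-deficient strain directly against H2O2-treated GS115, without the untreated library; strain and treatment differ together here. PAS_chr3_0932 was 878-fold higher in the hmt-deficient strain (781 to 991), at 10054 against 11.4 FPKM, with 1731 FPKM in untreated GS115. PAS_chr3_0440 was 185-fold higher (163 to 212), at 1158 against 6.26 FPKM. PAS_chr2-1_0016 was 102-fold lower (91.9 to 114), and PAS_chr1-4_0287 was listed at 0, at least 566-fold lower. Among 4966 genes, 1143 were at least 2-fold higher and 323 lower, with a median log2 ratio of 0.34. Of those past 2-fold 78.0% were higher, and 86.3% after rescaling to TPM. The authors' normalized columns, deposited for both of these libraries, gave 1488 higher and 235 lower (86.4% higher). Relative to the median, 697 were higher and 604 lower (53.6% higher). Of the 36 chromosome-end genes measured here, 23 (63.9%) were higher and 3 (8.33%) lower. Among other genes 22.7% were higher and 6.49% lower. The median log2 ratio of the end genes was 1.22 against 0.34 for other genes, above all random lists matched on expression. For 7 of the 8 ends the median lay above that of all genes. The 3 lower end genes, also named after the fact, were PAS_FragB_0077, PAS_c131_0020 and PAS_chr4_0008, and PAS_chr4_0008 stood at 10.4 FPKM untreated, 1435 after H2O2 and 115 in the hmt-deficient strain.

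Both conditions were then compared through their ratios to untreated GS115. Over 4998 genes, 243 were at least 2-fold higher in both and 362 lower in both. The lists would share 49.7 and 142 genes if independent. With each ratio centred on its median, 335 were higher in both, 256 lower in both and 37 opposite, and independent lists would share 96.7 higher and 72.0 lower genes. Simulated unchanged libraries that share the untreated one have no median shift, like the centred numbers, and gave 339 higher, 341 lower and 45.6 opposite. The centred lists held 782 higher and 747 lower genes after H2O2, and 618 and 482 in the hmt-deficient strain. The simulated lists were not matched to these sizes. These overlaps therefore cannot show whether the sharing exceeded what a common untreated library gives. Without centring, 3 genes were higher after H2O2 and lower in the hmt-deficient strain, and 43 showed the reverse. The 3, named after their values were seen, were PAS_chr2-1_0482 (918 FPKM untreated, 2179 after H2O2, 409 in the hmt-deficient strain), PAS_chr3_0870 (374, 1505 and 182 FPKM) and PAS_chr4_0198 (342, 977 and 125 FPKM). Across genes, which are not independent replicates, the log2 ratios correlated with Pearson r 0.60 and Spearman rho 0.50, beside a simulated r of 0.50. Their covariance was 0.76 beside a simulated 0.54. Both simulated values follow from the noise assumed, of equal size in the 3 libraries. They cannot show whether the observed values exceed what the shared library gives. With 1 untreated library the control could not be split, so part of the resemblance may come from that shared library. Log2 levels correlated at 0.83 between the H2O2-treated and hmt-deficient libraries, 0.80 between untreated and hmt-deficient, and 0.76 between untreated and H2O2-treated.

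**Figure D3:**
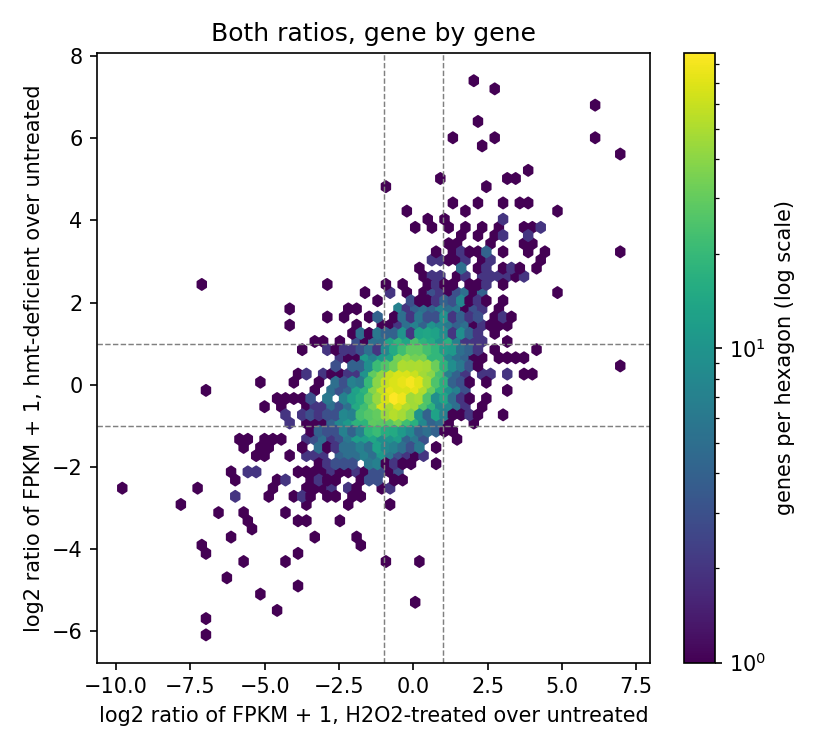
Log2 ratio of FPKM + 1 of H2O2-treated over untreated (horizontal) against hmt-deficient over untreated (vertical) for 4998 genes, 1 library per condition; colour gives genes per hexagon on a log scale and dashed lines mark 2-fold. The ratios share the untreated library, and 243 genes lie in the upper right and 362 in the lower left corner.

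Gene length separated the libraries as well. In the shortest of 5 equal bins of coding length (median 495 bp) the median log2 ratio of the hmt-deficient strain to untreated GS115 was -0.39, and 226 of 1000 genes were at least 2-fold lower against 92 higher. In the longest bin (median 2630 bp) the median was 0.11, with 55 genes lower and 102 higher. This difference of 0.50 lay outside the range of shuffles among genes of like expression (-0.07 to 0.09) and was 0.40 to 0.60 within each of 5 expression bins. Against the H2O2-treated library the longest bin exceeded the shortest by 0.84, beyond a shuffled range of 0.16 to 0.33. For H2O2 against untreated the difference was -0.36, inside the shuffled range of -0.37 to -0.18.

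**Figure D4:**
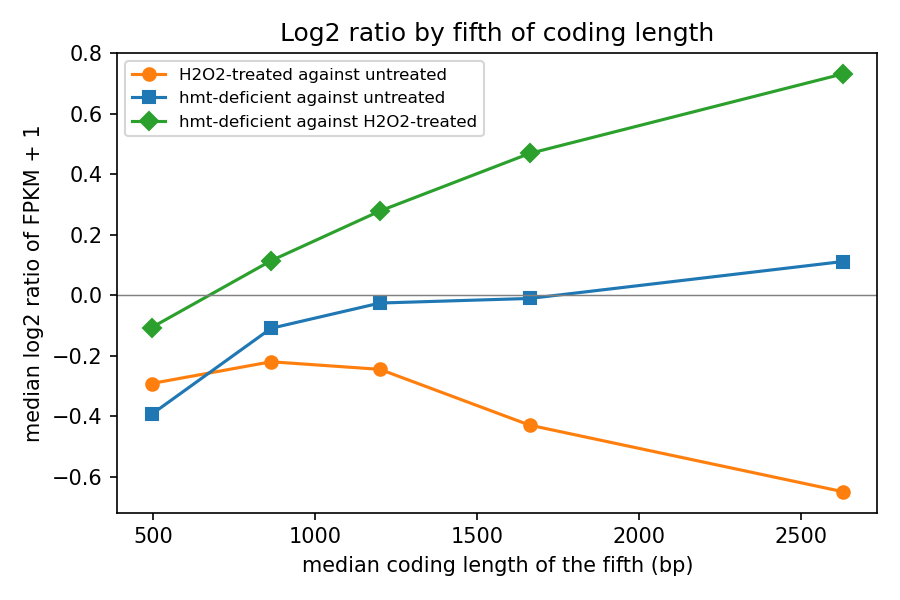
Median log2 ratio of FPKM + 1 in 5 equal bins of coding length, plotted at each bin's median length in bp, for the 3 pairs of libraries (1 library each). The hmt-deficient ratios are higher in longer genes, from -0.39 to 0.11 against untreated and from -0.11 to 0.73 against H2O2-treated.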

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

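The alternatives with the authors' normalized columns, without 9 odd untreated values, and those for chromosome ends, coding length and near-silent genes were chosen after seeing the data. The other settings were set before. Among the named genes they were applied to, PAS_chr1-4_0287 and PAS_chr1-1_0102 against untreated were picked after their values were seen. Of 222 alternative values, 168 stayed, 51 moved and 3 changed sign. Staying meant within 1.5 times the count, within the interval of the value or, for named genes, within 0.1 on the log2 scale. These values are not independent checks. Counts were scored in total and by direction, and no minimum and a minimum of 1 FPKM gave the same counts. A total could stay while both directions moved, as with centring after H2O2 (1510 genes in total). Centring on the median log2 ratio gave 767 higher and 743 lower genes after H2O2, and 697 and 604 for hmt-deficient against H2O2-treated; the trimmed mean of log ratios gave 767 and 743, and 695 and 607. By construction both remove the median shift. A 4-fold threshold, stricter by construction, gave 471 genes (129 higher, 342 lower) after H2O2, 266 (166, 100) for hmt-deficient against untreated and 320 (275, 45) for hmt-deficient against H2O2-treated. It left 80 genes higher in both, 66 lower in both and 2 opposite. Centring changed those higher in both from 243 to 335, those lower in both from 362 to 256 and the opposite ones from 46 to 37, each within 1.5 times the count. A minimum of 50 FPKM, which tests fewer genes, gave 743 higher genes for hmt-deficient against H2O2-treated. Spearman's rho was 0.50 against a Pearson r of 0.60; the cause was not tested.

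With 20 genes per chromosome end the difference from other genes was 0.40 in both hmt-deficient comparisons, against 1.08 and 0.88 with 5; the wider window takes in genes further inward. For H2O2 the difference of 0.31 became -0.017 with 10 genes per end, -0.0098 with 20 and -0.031 without the first end of chromosome 3; it was 0.70 with 3 genes per end, 0.62 without the first end of chromosome 1 and 0.68 without the last end of chromosome 2, and the cause was not tested. The 42 values of named genes kept their direction, with absolute log2 ratios of at least 2.32, but only 15 stayed within 0.1 on the log2 scale. The lowest was PAS_chr1-1_0102 in the hmt-deficient strain against untreated, which went from -4.39 to -2.32 with a pseudocount of 5. The kept direction is no check, because these genes were picked for ratios too large for such settings to reverse. Alternatives for gene lists were not run because the lists matched 0 genes, and those for replicate columns were not run because each file held 1 library. No paired analysis was possible because each group has 1 library. At 10 FPKM, a median-length untreated gene rests on 184 fragments (exact 95% interval 158 to 212), so depth limits mainly genes below that level.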

Other observations

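All tests in this part were chosen after the results were seen. Runs of neighbouring genes were also counted between the hmt-deficient and H2O2-treated libraries, with 66 runs of 3 or more higher genes against a shuffled mean of 46.6 (central 95% 37 to 58). The longest held 7 genes, PAS_chr4_0337 to PAS_chr4_0343, far from the chromosome ends (rank 348 or more). The correlation of log2 ratios between adjacent genes was 0.16 for hmt-deficient against untreated and 0.12 without the 20 outermost genes of each end, where shuffled gene order gave -0.03 to 0.03. For H2O2 against untreated it was 0.10. Medians by chromosome were close, from -0.11 on chromosome 1 to -0.03 on chromosome 2 for the hmt-deficient strain and from -0.43 on chromosome 1 to -0.36 on chromosome 3 after H2O2.

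PAS_chr1-4_0287 and PAS_chr1-1_0102 were listed at 0 in the hmt-deficient library alone. Too few fragments cannot account for this, since the lower of the expected numbers was 644. Loss of a segment spanning several genes is argued against by the 4 adjacent genes, the lowest of which stood at 24.4 FPKM in that library. Values set to 0 in the processing cannot be told apart from a true absence: 0 genes at 10 FPKM or more in the other libraries were at 0 in the untreated or the H2O2-treated library, but 2 genes are too few to decide. No biological explanation was tested, since the labels do not say which locus was altered and reads over these genes were not analysed here.

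Chromosome-end genes were higher in the hmt-deficient library. A low reading of the untreated library alone is argued against by the comparison with the H2O2-treated library, where their median log2 ratio was 1.22 and matched random lists ran from 0.17 to 0.86. Counting noise is argued against by all 40 end genes, taken whatever their ratio or level: the counting interval of the ratio lay above 1 for 33 and below 1 for 4, against 40.2% and 47.6% of other genes; variation between cultures is not covered by this. Reads shared between similar copies at chromosome ends cannot be told apart from a rise of single genes, because sequences were not compared; 8 of 8 ends lay above the median of all genes. A loss of gene silencing near chromosome ends in the hmt-deficient strain may be a hypothesis to follow up with replicate cultures. Strain and library are 1 and the same here. However, near-silent genes did not rise at the ends in particular. Of the 39 that reached 20 FPKM in the hmt-deficient library, 25.6% lay within 20 genes of an end. Among the 79 genes under 5 FPKM untreated that share was 24.1%.

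The log2 ratio of the hmt-deficient strain to untreated GS115 was higher in longer genes. A different length divisor in 1 library is argued against by the recovery of whole fragments with the same lengths: in each of 5 length bins of each library, agreement with whole numbers was at least 91.4% of what rounding allows. Expression level is argued against by the difference of 0.50 between the longest and shortest bins, outside the expression-matched range, and loss from the shortest genes alone by the 0.14 between the longest and middle bins (expression-matched range -0.08 to 0.08; 0.01 to 0.34 within 5 expression bins), although most of the 0.50 lay between the shortest and middle bins (-0.39 and -0.03). RNA fragmentation or size selection that differed between libraries may account for it and cannot be told apart from an effect of the strain, since the 0.84 against the H2O2-treated library also rests on 1 library per strain. An effect of the strain on long transcripts was not tested.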
